A study of Mus musculus with 12 samples.

How the data were processed

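Small RNA abundance was measured by sequencing in kidneys of C57BL/6 mice, an inbred laboratory strain. Per the labels' protocols, mice received saline or glyoxylate by intraperitoneal injection (75 mg/kg per day in 200 µl, days 1 to 7), the kidneys were taken at death after day 7 and frozen, RNA was extracted with Trizol, and libraries were built with an Illumina TruSeq kit. Glyoxylate is a metabolic precursor of oxalate, and its injection is used to form calcium oxalate deposits in the mouse kidney. Groups were assigned from the treatment label, with 6 saline and 6 glyoxylate libraries, and every library mapped to 1 column of the table, so 0 columns of values were left unmapped. The protocol speaks of each mouse and the titles number the samples, but no label identifies an animal, so p-values measure the spread between these samples. The series text speaks of pairs, but a shared replicate number alone was not taken as a pair, so the main test was unpaired.

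The deposited table holds RPM (reads of a miRNA for every 1000000 reads of its library) for 230 miRNAs in 12 libraries, of which 185 carry mouse miRNA names and 45 are candidate miRNAs numbered by the authors. The submitters' processing notes name Bowtie 0.12.2 and the mouse builds mm8 and mm9, without saying what each was used for, and the trimming, counting and calling steps are not given in the sources used here. Within each library every RPM value was a whole multiple of 1 step (100% of values within 0.001 reads of a whole number), and 1 read was worth between 0.0734 RPM in saline 1 and 0.219 RPM in glyoxylate 4. The library totals given below follow from these steps. The reads themselves were not used for a count-based test, because in most libraries the table holds too few low values for an independent check of the step, and the test fixed for normalized values was used in place of the one fixed for counts.

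The table is, by its title, one of differentially expressed miRNAs. Its rows take only part of each library's reads, and the rule that chose them is not given in the sources used here. Abundant kidney miRNAs that did not enter the table were not analysed here, the Benjamini-Hochberg adjustment covers only the listed rows, and the number of calls, the share of rows that pass and the separation of the libraries are not independent evidence of an effect of glyoxylate. A second deposited file, a functional annotation of 21148 genes in 14 columns, holds no expression values and no miRNA targets and was not used here, so the planned mRNA, gene list and target comparisons were not run.

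Rows at 1 RPM or more in at least 6 libraries were tested, which kept 143 and left out 87. Values were log2(RPM + 1) and the groups were compared with limma 3.58.1 (R 4.3.3), with an intensity trend in the prior variance, no covariate and Benjamini-Hochberg adjustment over the 143 rows. A call is an adjusted p under 0.05. Fold changes are glyoxylate against saline on the log2(RPM + 1) scale, which understates changes of rare miRNAs, and the error given with them is limma's standard error. The same code was run on 20 simulated tables with the 230 real means and library totals, where 60 miRNAs were changed. The spread beyond counting error was the same for every row (dispersion 0.04), and more variable rows were not simulated. Of the changed miRNAs that passed the filter, it called 65.2% of 256 at 1.5-fold, 94.6% of 261 at 2-fold and 100% of 250 at 4-fold. Changed miRNAs that the filter removed are not in these shares. Of its calls 3.49% were false.

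Single values such as library totals were compared with a two-sided exact permutation test over the 924 assignments of 6 against 6, whose smallest p is 0.00216. Lists of miRNAs were fixed before the data were examined, as were the main test, the alternatives planned and the rule for named miRNAs. Because the rows had been selected, competitive list tests were not run. Each list with at least 3 tested members was compared with the table's own share of fitted changes above 0 (51.7%). This used a two-sided exact binomial test of signs, adjusted over 13 lists and meant as a description. Each alternative used its own share and its own lists of at least 3 tested members. On rows at 1 RPM or more in all 12 libraries these were 52.0% and 11 lists. Members of a list that come from 1 precursor are not independent, nor are those of 1 locus if they act together. The sign test treats them all as if they were. Lists of 3 or 4 members could not pass it whatever their signs (smallest possible p 0.112 and 0.0542), so their sign tests carry no information. Named miRNAs were those with the 12 largest rises and 12 largest falls among calls at or above the median level, the 5 most abundant, and for each list the 4 members with the smallest p (all tested members of the leukocyte, erythroid and liver or muscle lists). Any other miRNA named is said to have been chosen after its values were seen.

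Precursors were looked up by name in GENCODE release M21, an annotation of a later mouse build than those in the submitters' notes. The annotation matched 171 of the 185 named rows and was used only for chromosomes, host genes and neighbours, and no coordinates are given. Rows that cannot be told apart by sequence share their reads: miR-486a-5p and miR-486b-5p differed by at most 1.59 RPM in any library, and miR-669a-5p and miR-669p-5p had identical values. Counting error was small for abundant miRNAs. The 95% exact binomial (Clopper-Pearson) interval of miR-21a-5p's share of reads was at most 0.0799 percentage points wide. Intervals of this kind cover counting error only, since PCR copies are not independent molecules. The alternatives tried were pseudocounts of 0.1 and 10, no filter, the replicate number as a block, each library left out, an adjusted p under 0.01 and an added log2 fold bound of 1. Those added after seeing the data were a library total without miR-21a-5p, scaling to the reads outside the table, thinning to the shallowest library, a mean of 10 RPM or more, leaving out the library of each group farthest from its group mean (saline 6 and glyoxylate 4), and for the lists, miR-486a-5p and miR-486b-5p counted as 1 member and rows at 1 RPM or more in all 12 libraries. A level cut from the saline libraries alone was added for the ratios between leukocyte miRNAs. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.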

Results

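miRNAs of whole mouse kidney were sequenced after 7 days of glyoxylate, a model of calcium oxalate nephrocalcinosis, and after saline, with 6 libraries in each group. The comparison asks which kidney miRNAs change when oxalate deposits form. Library totals were 9.93 ± 2.17 M reads with saline (M, 1000000; SD, n = 6, range 7.57 to 13.6 M) and 7.31 ± 2.35 M with glyoxylate (SD, n = 6, range 4.57 to 10.5 M). This difference did not pass an exact permutation test (p = 0.0779). The 230 listed miRNAs took 16.6% ± 0.964 of the reads with saline and 34.7% ± 1.72 with glyoxylate (SD, n = 6 each, exact permutation p = 0.00216, the smallest possible).

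miR-21a-5p, known to rise in injured and fibrotic kidney, gained 18.8 percentage points of the reads, against 18.1 points for all listed miRNAs together. It made up 6.23% ± 0.400 of all reads in saline kidneys and 25% ± 1.8 in glyoxylate kidneys (SD, n = 6 each), a 4.01-fold rise (exact permutation p = 0.00216). miR-146b-5p, induced by inflammatory signalling, and miR-147-3p, induced in activated macrophages, rose with it, as did myeloid miR-223-3p and miR-223-5p. The red cell miRNAs miR-451a, miR-144-3p and miR-486a-5p fell to between 0.140 and 0.205 of their saline means, and the abundant kidney miRNAs miR-30c-5p and miR-378a-3p fell to 0.574 and 0.526 of theirs. Of the 143 miRNAs tested, limma gave a call at an adjusted p under 0.05 to 126, 58 higher and 68 lower with glyoxylate, and 131 had an unadjusted p under 0.05. Since the authors had already selected the listed miRNAs by an unstated rule, this count is not independent evidence of a widespread change.

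A rise of miR-21a-5p lowers the RPM of every other miRNA. Leaving its reads out of the library totals shifted the log2 fold changes upward by 0.32, and scaling to the reads outside the table by 0.35, before the pseudocount is added. The calls were then 75 higher and 59 lower in the first case and 77 higher and 53 lower in the second, so that the share of higher calls went from 46.0% to 56.0% and 59.2%. Of the 68 lower calls 57 and 51 were still called lower, all 58 higher calls were still called higher, and no called miRNA turned its sign under any alternative tried.

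**Figure D1:**
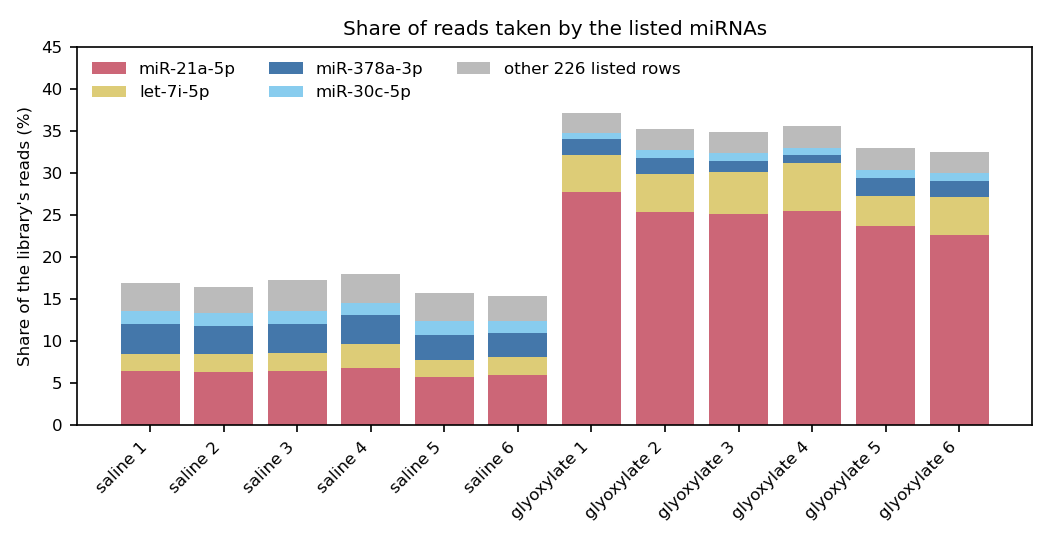
Share of each library's reads (percent) taken by 4 abundant listed miRNAs and by all other listed rows, stacked, for the 6 saline and 6 glyoxylate libraries. miR-21a-5p took between 5.69% and 6.76% of the reads in the saline libraries and between 22.6% and 27.8% in the glyoxylate libraries.

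All 10 tested members of the injury and fibrosis list rose, with a median log2 fold change of 1.16 (exact binomial adjusted p = 0.0134). Of its 25 fixed members 11 were among the rows of the table, and the rest were not analysed here. The list holds both arms of miR-21a, miR-214, miR-132 and miR-212, and the sign test counts them as if they were independent. It was not repeated with 1 member for each precursor. miR-21a-5p, annotated on chromosome 11 within an exon of Vmp1, went from 62292 ± 3999 to 249910 ± 17612 RPM (SD, n = 6 each), a log2 fold change of 2.0 ± 0.06 (SE, limma adjusted p = 3.89e-13). The opposite arm of its precursor, miR-21a-3p, was rare and rose by 1.49 ± 0.22 from 8.21 to 25.2 RPM. miR-212-5p and miR-132-3p, neighbours on chromosome 11 whose transcription responds to CREB, rose by 1.64 ± 0.22 and 1.36 ± 0.26. miR-199a-5p, which has a copy beside miR-214 in the Dnm3os transcript of fibroblasts, doubled from 669 ± 68.8 to 1357 ± 194 RPM (log2 fold change 1.01 ± 0.13, adjusted p = 1.83e-05). The mesenchymal list had 3 tested members, of which miR-199a-5p and miR-214-3p (0.99 ± 0.21), both also on the injury list, rose and miR-145b fell (-0.53 ± 0.16, at 1.78 RPM in saline kidneys). The miR-145b call was lost with scaling to the reads outside the table (adjusted p = 0.0588) and after thinning (adjusted p = 0.179).

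All 11 tested leukocyte miRNAs rose as well (median log2 fold change 1.19, exact binomial adjusted p = 0.0134). The list was fixed with 15 members, and the others, among them miR-150-5p and miR-146a-5p, were not among the rows of the table. miR-150-3p, outside the list and named after its values were seen, went from 0.741 to 0.186 RPM and was not tested. miR-146b-5p, in an intron of Mfsd13a on chromosome 19, went from 232 ± 37.3 to 936 ± 390 RPM (SD, n = 6 each, log2 fold change 1.94 ± 0.22, limma adjusted p = 6.19e-06). miR-147-3p went from 2.99 ± 1.13 to 17.7 ± 5.42 RPM (2.25 ± 0.25, adjusted p = 5.63e-06). The arms of miR-223, a neutrophil and monocyte miRNA on chromosome X, rose by 1.31 ± 0.24 for miR-223-3p and 1.38 ± 0.21 for miR-223-5p. miR-511-3p, from an intron of the macrophage gene Mrc1, rose by 1.19 ± 0.23 from 0.749 RPM, and miR-342-3p, from an intron of Evl, by 1.04 ± 0.25. The smallest rises were those of miR-142a-3p (0.59 ± 0.19, adjusted p = 0.0124), found in all blood cell lineages, and miR-155-5p (0.53 ± 0.18, adjusted p = 0.0148), which is induced in activated lymphocytes and macrophages. Of the 11, 6 were at 1 RPM or more in all 6 saline libraries. The filter fixed the sign of part of the others: miR-147-5p (0.382 RPM) and miR-511-5p (0.358 RPM) passed it through the glyoxylate libraries alone, and a fall would have left them untested. miR-511-3p was close to this, since it passed only with saline 2 (1.28 RPM) in place of glyoxylate 5 (0.898 RPM). It was tested in 12 of 21 alternative fits. On rows at 1 RPM or more in all 12 libraries the list's sign test did not pass (6 members, all higher, median 1.18, adjusted p = 0.0879). Nor did it at a mean of 10 RPM or more (adjusted p = 0.0625). That of the injury list passed in both cases (adjusted p = 0.0230 and 0.0313). Both lists count the arms of 1 precursor as separate signs, so this contrast does not show the injury list to be the firmer. The adjusted p of the leukocyte list's sign test was 0.0508 to 0.0509 without glyoxylate 1, glyoxylate 4 or glyoxylate 6, and its median was then 1.01 to 1.22. With any glyoxylate library left out, miR-147-5p and miR-511-5p no longer passed the filter, so the list was shorter. The size of the median depended on the pseudocount and was 0.56 with a pseudocount of 10.

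**Figure D2:**
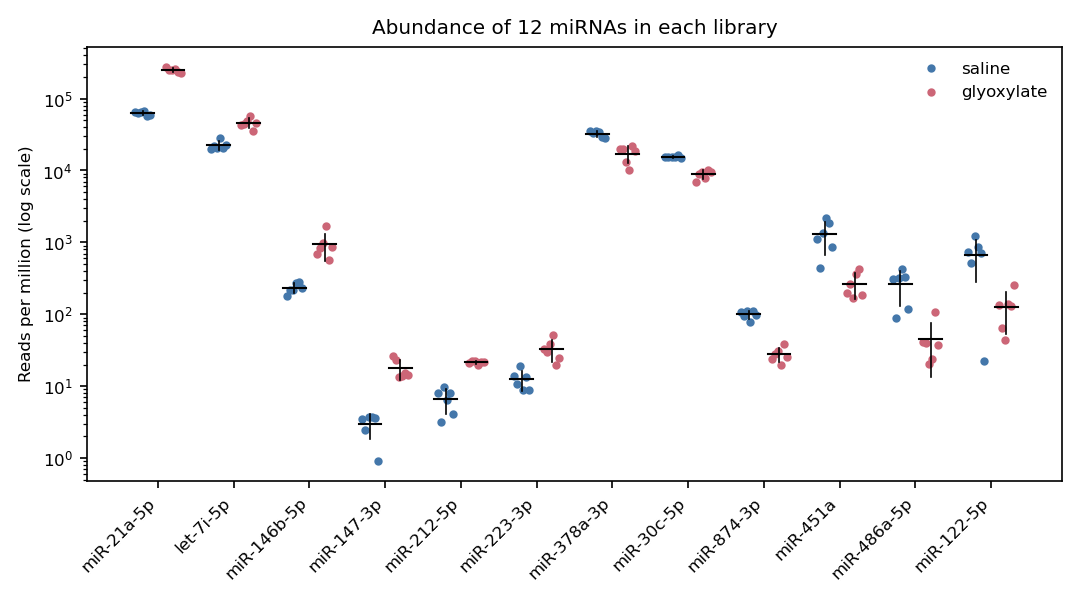
Abundance of 12 miRNAs in RPM (log axis), with 1 point per library for saline (blue) and glyoxylate (red); horizontal lines are means of 6 libraries and vertical lines 1 SD either side, drawn no lower than 0.02 of the mean. The groups do not overlap for miR-21a-5p, miR-30c-5p or miR-451a, and the saline 6 library has the lowest miR-122-5p (22.3 RPM).

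Several abundant kidney miRNAs fell in the same libraries in which the leukocyte list rose (median 1.19) and the erythroid list fell (median -2.37). miR-378a-3p, from an intron of the mitochondrial co-activator gene Ppargc1b on chromosome 18, went from 32671 ± 3027 to 17173 ± 4498 RPM (SD, n = 6 each, log2 fold change -0.97 ± 0.16, limma adjusted p = 0.000116). All 4 listed miR-30 family members fell, with a median of -0.85, among them miR-30c-5p from 15494 ± 628 to 8895 ± 1248 RPM (-0.81 ± 0.10) and miR-30e-3p from 4011 ± 98.3 to 2102 ± 462 RPM (-0.96 ± 0.14). All 4 listed members of the miR-29 family also fell (median -0.90), for example miR-29c-3p (-1.04 ± 0.19) and miR-29c-5p (-0.98 ± 0.14). The others were miR-29a-5p and miR-29b-1-5p. The 3p arms of miR-29a and miR-29b were not among the rows of the table, so they were not analysed here. The same holds for the 5p arms of miR-30a, miR-30d and miR-30e. The miR-30 list was fixed with 11 members and the miR-29 list with 7, so these falls are not shown for either family as a whole. A list of 4 cannot pass the exact binomial test of signs (smallest possible p = 0.0542), so the adjusted p of 0.117 for each family carries no information. Of the kidney-enriched list miR-203-3p (-0.95 ± 0.15), miR-192-3p (-0.87 ± 0.24) and miR-193b-3p (-0.71 ± 0.19) fell and miR-215-5p rose (1.01 ± 0.40, adjusted p = 0.0287). This list was fixed with 19 members, of which 5 were among the rows of the table and 4 were tested. miR-192-5p, miR-194-5p and miR-204-5p were among the absent members. miR-215-5p was uneven, with 56.5 RPM in glyoxylate 1 against 7.07 to 19.7 RPM in the other glyoxylate libraries. Its fold change was 0.65 without that library, and its adjusted p was 0.0565 to 0.0577 without saline 2, saline 6 or glyoxylate 4 and 0.0999 without the latter 2 together. Without miR-21a-5p in the totals the medians were -0.53 for miR-30, -0.60 for miR-29 and -0.54 for the kidney-enriched list, and all 4 miR-30 calls held with scaling to the reads outside the table, while the miR-29 calls did so in 3 of 4 (miR-29b-1-5p was lost with either scaling, adjusted p = 0.106 and 0.125). The miR-193b-3p call was lost with the latter scaling (adjusted p = 0.0519).

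The 12 largest falls among calls at or above the median level also held miRNAs outside the lists. miR-874-3p, in an intron of Klhl3, a regulator of salt transport in the distal nephron, went from 99.9 ± 12.8 to 27.7 ± 6.39 RPM (SD, n = 6 each, log2 fold change -1.83 ± 0.17, adjusted p = 1.75e-06). miR-107-3p, in an intron of the pantothenate kinase gene Pank1, fell from 719 ± 57.1 to 319 ± 41.2 RPM (-1.18 ± 0.13), and miR-455-3p, in an intron of the collagen gene Col27a1, and miR-190a-5p, in an intron of Tln2, fell too (-1.21 ± 0.17 and -1.10 ± 0.21), as did miR-203b-3p (-1.37 ± 0.23), miR-3073b-5p (-1.23 ± 0.26) and miR-1968-5p (-1.18 ± 0.22). In each of these the groups did not overlap, as in 58 of the 143 tested miRNAs. Chance gives 0.216% for an unselected row, and because the authors selected these rows the count cannot be set against it.

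The erythroid miRNAs had the lowest median of the 13 lists tested. All 6 tested members had fitted changes below 0, with a list median of -2.37 (exact binomial adjusted p = 0.0410), and 5 were called lower. miR-451a went from 1303 ± 644 to 268 ± 106 RPM (SD, n = 6 each, log2 fold change -2.19 ± 0.35, limma adjusted p = 8.94e-05). miR-144-3p, its neighbour on chromosome 11, and miR-144-5p from the same precursor fell too (-2.65 ± 0.43 and -2.15 ± 0.33). miR-486a-5p and miR-486b-5p, which share reads and are in effect 1 measurement, were lower with log2 fold changes of -2.55 ± 0.43 and -2.56 ± 0.43. miR-486a-3p, at 2.48 RPM in saline kidneys, did not pass (-0.73 ± 0.34, adjusted p = 0.0511), but passed without saline 2 (-1.02, adjusted p = 0.00370), with no filter (0.0493) and with a pseudocount of 10 (0.0374). The sign test took miR-486a-5p and miR-486b-5p as 2 members, and with the pair counted as 1 it did not pass (median -2.19, adjusted p = 0.0818). The sign test over this short list was not stable. Its adjusted p was 0.0508 to 0.102 without saline 1, 3, 4, 5 or 6 or glyoxylate 1, 4, 5 or 6. Without saline 1, 3, 4, 5 or 6 or glyoxylate 6, miR-486a-3p no longer passed the filter, so the list had 5 members. The adjusted p was 0.102 without miR-21a-5p in the totals, where the median was -2.08. On rows at 1 RPM or more in all 12 libraries it was 0.0879 with 5 members.

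miR-122-5p, a hepatocyte miRNA, was at 678 ± 394 RPM in saline and 128 ± 74.0 RPM in glyoxylate kidneys (SD, n = 6 each, log2 fold change -1.97 ± 0.77, limma adjusted p = 0.0268). Saline 6 held 22.3 RPM against 518 to 1209 RPM in the other saline libraries, and without it the fold change was -2.81 (adjusted p = 3.41e-05). The call was lost without saline 1, 3, 4 or 5 or glyoxylate 2 or 3 (adjusted p 0.0518 to 0.0614) and with either other scaling (0.0545 and 0.0592). Of the muscle miRNAs on the same list, miR-499-5p, in an intron of the myosin gene Myh7b, fell from 3.72 to 1.10 RPM (-1.17 ± 0.20), and miR-206-3p was at 0.33 ± 0.25 (adjusted p = 0.203, and 0.0453 and 0.0419 with the other scalings).

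**Figure D3:**
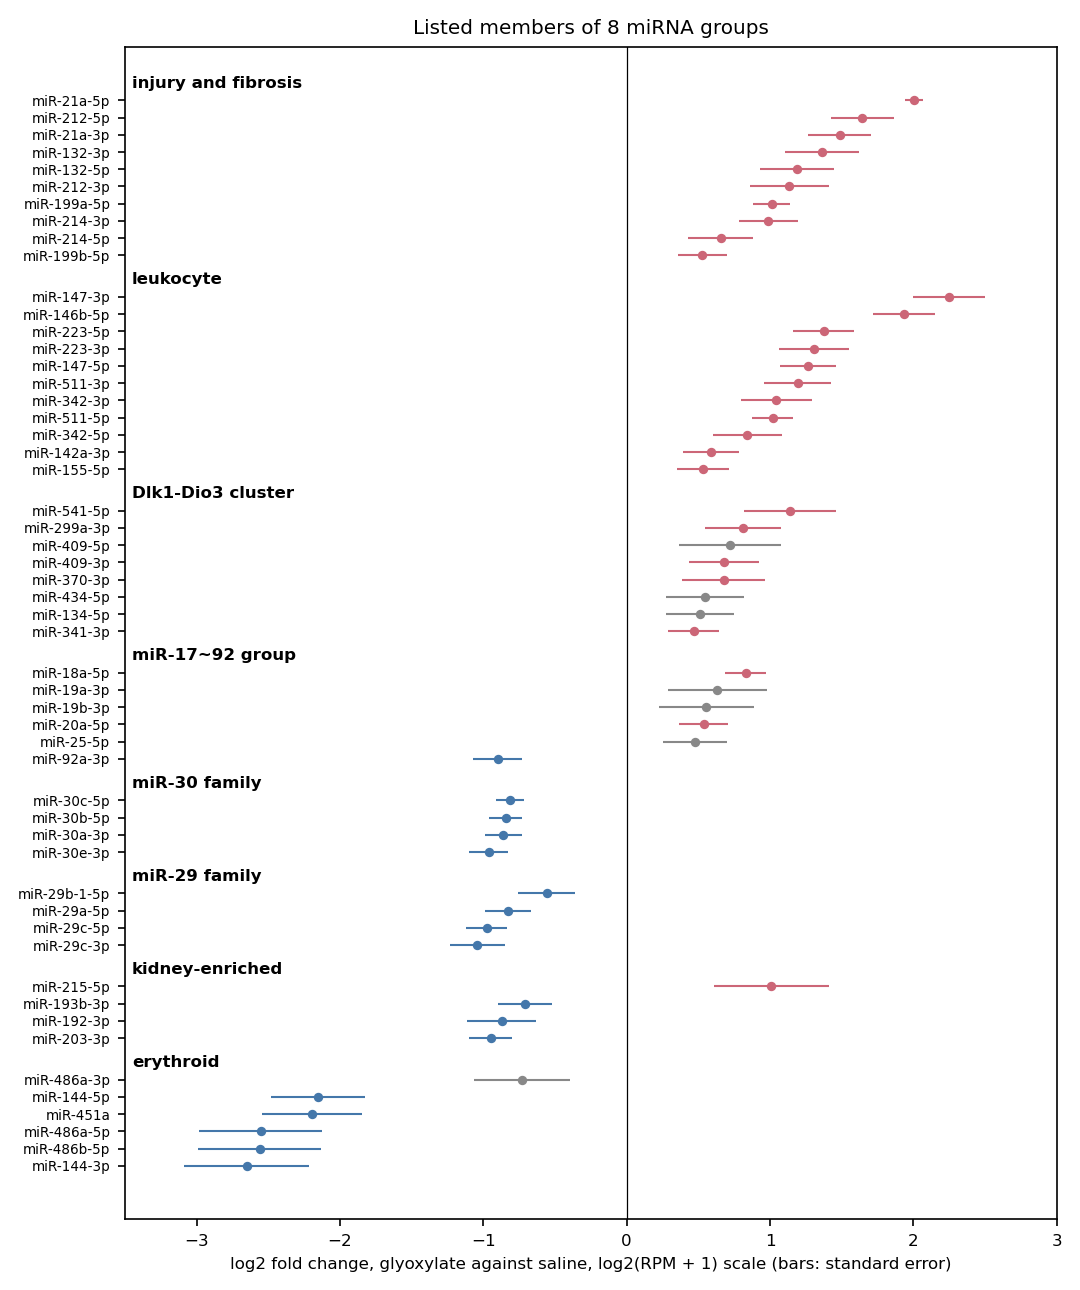
log2 fold change of glyoxylate against saline on the log2(RPM + 1) scale (x axis) for the tested members of 8 fixed miRNA lists, with bars for the standard error; red marks higher calls, blue lower calls and grey no call. All 10 injury and 11 leukocyte miRNAs lie above 0 and all 6 erythroid miRNAs below 0.

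The list of the imprinted Dlk1-Dio3 cluster on chromosome 12 was fixed with 52 members, of which 11 were among the rows of the table. All 8 tested members had fitted changes above 0 (median 0.68, exact binomial adjusted p = 0.0350), and 5 of the 8 were called higher. They include both arms of miR-409, and the sign test counts all 8 as if they were independent. Its p is too small if they act as 1 locus. miR-541-5p was the most abundant of them and went from 18.3 to 44.6 RPM (log2 fold change 1.14 ± 0.32), while miR-299a-3p (0.81 ± 0.27), miR-409-3p (0.68 ± 0.24) and miR-341-3p (0.47 ± 0.18, adjusted p = 0.0236) rose from 4.99 RPM or less. The others were named after their values were seen. miR-370-3p (0.68 ± 0.29, adjusted p = 0.0392), at 0.858 RPM in saline kidneys, kept its call in 8 of the 12 alternatives that tested it (adjusted p up to 0.0799). The 3 without a call were miR-134-5p (0.51 ± 0.24), miR-409-5p (0.72 ± 0.35) and miR-434-5p (0.55 ± 0.27), and with scaling to the reads outside the table all 8 passed. The list's median was 0.23 with a pseudocount of 10. Outside the list, and named after its values were seen, miR-1247-3p in an exon of Dio3os on chromosome 12 was lower (-0.66 ± 0.25, adjusted p = 0.0231). miR-329-5p, a neighbour of miR-299a named in the same way, had no call (0.67 ± 0.34, adjusted p = 0.0683). On rows at 1 RPM or more in all 12 libraries the list's sign test did not pass (6 members, adjusted p = 0.0879). The list's adjusted p was 0.0508 to 0.0725 without saline 1 or 5 or glyoxylate 1, 4, 5 or 6, and the miR-341-3p call was lost without saline 2, saline 6 or glyoxylate 6 (adjusted p 0.0513 to 0.0577). Without saline 6 and glyoxylate 4 together the miR-341-3p and miR-409-3p calls were both lost (adjusted p = 0.0902 and 0.0512). glyoxylate 6 stood apart for miR-409-3p (9.20 RPM against at most 3.99 RPM in the other glyoxylate libraries) and for miR-299a-3p (14.9 against at most 9.86 RPM). In the hypoxia and stress list the neighbours miR-183-5p (0.77 ± 0.12), miR-182-5p (0.60 ± 0.14) and miR-96-5p (0.58 ± 0.18) on chromosome 6 rose, as did miR-155-5p, while hypoxia-induced miR-210-3p fell (-0.75 ± 0.18), a call lost with scaling to the reads outside the table (adjusted p = 0.0555), and the sign test did not pass (adjusted p = 0.489). let-7i-5p, among the most abundant miRNAs listed, doubled from 22297 ± 3261 to 45945 ± 7035 RPM (1.04 ± 0.11, limma adjusted p = 4.75e-06), and let-7j rose and let-7b-3p fell (0.80 ± 0.20 and -0.82 ± 0.16).

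Members of the miR-17~92 group went both ways, with miR-18a-5p (0.83 ± 0.14) and miR-20a-5p (0.54 ± 0.17) higher, miR-92a-3p lower (-0.90 ± 0.17) and 3 of the 6 without a call (list adjusted p = 0.408). These were miR-25-5p (0.48 ± 0.22), miR-19a-3p (0.63 ± 0.34) and miR-19b-3p (0.56 ± 0.33), the last pair named after their values were seen, and all 6 passed with scaling to the reads outside the table. miR-25-5p, with an adjusted p of 0.0527, passed in 8 alternatives (0.0147 to 0.0499), among them both other scalings, the replicate block and no filter. miR-7a-5p (0.69 ± 0.23) and the islet miRNA miR-375-3p (0.74 ± 0.25) rose in the list of adrenal, nerve and pancreas miRNAs, and miR-7b-5p did not pass (0.93 ± 0.48, adjusted p = 0.0762), with 34.4 RPM in glyoxylate 4 and a fold change of 0.45 without that library. It passed without glyoxylate 1 (adjusted p = 0.0234) and with both other scalings (0.0353 and 0.0330). Adjusted over the list alone, as many members passed in each of the 13 lists tested, except for 6 in the erythroid list and 4 in the Dlk1-Dio3 list. None of the 4 endothelial and 10 miR-200 family miRNAs fixed as lists was among the rows of the table, so they were not analysed here.

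All 13 tested candidate miRNAs numbered by the authors were called, 6 higher and 7 lower, but 7 of the 13 lost the call in some alternatives and kept it in 8 to 17 of 20. Of all 126 calls, 96 held in every alternative fit that tested the miRNA and 30 were lost in at least 1. novel_miR_455 had the largest fall of any tested row, from 1056 ± 941 to 132 ± 107 RPM (SD, n = 6 each, log2 fold change -2.84 ± 0.64, limma adjusted p = 0.00125), with saline libraries between 194 and 2616 RPM. Of the 45 candidates 43 had a mean below 10 RPM. In all, 38 calls reached a 2-fold change, 19 in each direction. The first principal component of the 143 tested miRNAs held 66.9% of the variance and separated the groups by 12.2 (exact permutation p = 0.00216), which the selection of the rows favours.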

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

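The tests of explanations in this part were chosen after the results were seen. In 13 of 142 groups of 6 values, from 69 named miRNAs and 2 measures of the libraries (total and the listed rows' share of reads), 1 library stood apart from the other 5 (gap over range above Dixon's 95% critical value), where chance gives about 7.1. The highest library was glyoxylate 5 for miR-486b-5p, miR-486a-5p and miR-144-3p (gap ratios 0.758, 0.761 and 0.663), with miR-486a-5p at 106 RPM against at most 40.7 RPM in the others. It was also the highest for miR-145b (0.707) and the lowest for miR-183-5p (0.701). glyoxylate 6 was the highest for miR-486a-3p (0.635), miR-299a-3p (0.626) and miR-409-3p (0.732). miR-7b-5p was high in saline 5 (0.674) and in glyoxylate 4 (0.814), and miR-215-5p in glyoxylate 1 (0.744). let-7i-5p was high in saline 4 (0.705) and miR-199a-5p low in saline 6 (0.718).

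The fall of the erythroid miRNAs is a pattern with several candidate explanations. Reads taken up by miR-21a-5p do not account for it, since their median log2 fold change was still -2.08 with those reads left out of the totals, against -2.37 before. Less blood left in the glyoxylate kidneys may account for it: miR-451a and miR-486a-5p come from separate loci, and their deviations from the group means went together over the 12 libraries (Pearson r = 0.783, permutation p = 0.00462, adjusted p = 0.00924 over 2 relations; Spearman rho = 0.860, permutation p = 0.00116; r = 0.631 without the 2 libraries farthest from the median). The relation was clear among the 6 saline libraries (r = 0.930, exact permutation p = 0.00278) and not past the threshold among the 6 glyoxylate libraries (r = 0.554, exact permutation p = 0.306). A lower number of immature red cells under glyoxylate would give the same pattern and was not tested.

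miR-122-5p fell by a similar amount, and the same blood is a candidate source. Its deviations and those of miR-451a had r = 0.320 (permutation p = 0.403, adjusted p = 0.403; Spearman rho = 0.399, permutation p = 0.216; r = 0.421 without the 2 libraries farthest from the median), which leaves this open with 12 libraries. The low saline 6 library had 853 RPM of miR-451a, within the saline range of 443 to 2173 RPM. An effect of glyoxylate on hepatocyte RNA in the circulation was not tested.

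The 68 lower calls could come from miR-21a-5p taking up reads, or from the smaller glyoxylate libraries. With miR-21a-5p reads left out of the totals their median log2 fold change went from -0.87 to -0.62 (quartiles -0.79 and -0.49), so displacement accounts for part of the falls and not for the whole. After thinning every library to 4566085 reads, 65 of the 68 were still called lower, which argues against depth. The reads thinned were those worked out from the RPM steps, which had no independent check in most libraries. An effect of glyoxylate on the kidney cells, or a smaller share of tubular cells among those sampled, stays open and was not tested.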

How the results depend on the processing

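The alternatives on scaling, thinning, the 10 RPM mean, the left-out pair of libraries, miR-486 counted as 1 member and rows at 1 RPM in all 12 libraries were chosen after seeing the data. The 126 calls (58 higher, 68 lower) became 192 (88 and 104) with no filter, which tests more rows, 78 (37 and 41) at a mean of 10 RPM or more, which tests fewer, and 38 (19 and 19) with a 2-fold bound, while an adjusted p under 0.01 left 90 (34 and 56). Pseudocounts of 0.1 and 10 gave 122 and 126 calls, sharing 121 and 125 with the 126. Leaving out 1 library gave 114 to 123, and leaving out saline 6 and glyoxylate 4 gave 105, all 105 among the 126. With the replicate number as a block there were 124 calls, of which 122 were shared. The series text speaks of pairs. The correlations of same-numbered deviations were 0.449, -0.132, -0.410, 0.293, 0.0271 and -0.187, and 2 of the 6 saline libraries correlated best with their own number. These few values gave no clear sign of pairing by number and cannot exclude it.

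List medians kept their sign throughout, but their size followed the pseudocount where members are rare. With 10 they were 0.56 for leukocyte, 0.23 for Dlk1-Dio3, -1.84 for erythroid, -0.30 for liver and muscle and -0.31 for kidney-enriched miRNAs, and with 0.1 the first 4 were 1.46, 0.91, -2.51 and -1.75. The sign tests did not change with it. With 1 library left out they ranged from -2.74 to -2.22 for erythroid, 0.47 to 0.82 for Dlk1-Dio3 and 1.01 to 1.40 for leukocyte miRNAs, and the sign test was lost in part of these. That test was also lost for erythroid miRNAs without miR-21a-5p in the totals (-2.08), after thinning (-2.37), with miR-486 counted as 1 member (-2.19, adjusted p = 0.0818), at 10 RPM or more (-2.55) and without saline 6 and glyoxylate 4 (-2.61), for Dlk1-Dio3 miRNAs after thinning (0.62) and without that pair (0.48), and for leukocyte miRNAs at 10 RPM or more (1.31) and without that pair (0.98). On rows at 1 RPM or more in all 12 libraries it was lost for erythroid (-2.55), Dlk1-Dio3 (0.61) and leukocyte miRNAs (1.18). The short lists hold few signs, and the filter stayed at 6 libraries when 1 was left out. miR-486a-3p, miR-147-5p and miR-511-5p were tested in 13 of 21 alternative fits and miR-511-3p and miR-370-3p in 12, and in the others their lists were shorter. Any further cause was not tested. Of 1382 comparisons of 68 single miRNAs with an alternative, 1343 kept their call or lack of one, 23 lost a call, 16 gained one and none reversed; miR-122-5p lost its call in 8, miR-215-5p and miR-341-3p in 4 each. Depth limits the rare rows: 3 reads are worth 0.220 RPM in saline 1 and 0.657 RPM in glyoxylate 4. Thinning used reads worked out from the RPM steps. The alternatives that belong to a count-based test, or that need competitive list tests, the authors' own fold changes, mRNA values or targets, were not run.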

Other observations

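All tests in this part were chosen after the results were seen. The arms of 1 hairpin had fitted changes of the same sign, whether called or not. Of the 19 precursors matched by name with both arms tested, 19 had both arms on the same side of 0 (both called in 17), where random pairing of the tested rows gave a mean of 9.45 (permutation p = 1e-05, the smallest that 100000 permutations can give). miR-378a-5p and miR-378a-3p were at -0.97 and -0.97 and miR-22-5p and miR-22-3p at -0.88 and -0.81, while the arms of miR-874 (-0.83 and -1.83) and miR-147 (1.27 and 2.25) differed in size. The arms of miR-301a and miR-486a, whose names matched no precursor, were left out. Neighbouring precursors had fitted changes of 1 sign in 10 of 10 groups within 10000 bases of one another (random mean 4.19, permutation p = 0.00019). Every member was called in 6 groups and none in 1. Among the groups were miR-212 and miR-132, the miR-182, miR-96 and miR-183 group, miR-29a and miR-29b-1, and miR-467e, miR-669c and miR-669o on chromosome 2. The groups of miR-341 and miR-370, of miR-299a and miR-329, and of miR-134, miR-541 and miR-409 all lie in the Dlk1-Dio3 cluster on chromosome 12. The permutation counted them as separate groups, so its p is too small if they act as 1 locus. A shared transcript is a candidate explanation for the common sign of arms and of neighbours. Outside this count, since its name matched no single precursor, miR-92a-3p (-0.90) went against miR-18a-5p (0.83) and miR-20a-5p (0.54) of the miR-17~92 locus, and it is also made from a further locus. miRNAs named only in this paragraph were chosen after their values were seen.

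A single uniform rise in leukocyte RNA might lie behind the 11 leukocyte miRNAs. It predicts that the others keep their ratio to miR-142a-3p, and the median log2 ratio of 6 members with a mean of 10 RPM or more over the 12 libraries changed by 0.55 (exact permutation p = 0.0519), which does not settle it. miR-147-3p, at 2.99 RPM in saline kidneys, reached that level only through its own rise, and with the cut taken from the saline libraries, which left 5 members, the change was 0.46 (exact permutation p = 0.195). Taken singly over 6 tests, miR-147-3p (1.66), miR-146b-5p (1.35), miR-223-5p (0.79) and miR-223-3p (0.72) rose relative to miR-142a-3p (exact permutation adjusted p = 0.00433, 0.00433, 0.00433 and 0.00649), and miR-342-3p (0.46) and miR-155-5p (-0.06) did not pass (0.234 and 0.823). miR-146b-5p is also made by kidney epithelium, so a change in the kind of leukocyte and induction in resident cells both stay open.

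Other splits of the 12 libraries say little here. Of 100 splits of 6 against 6, the real one gave 126 calls and the highest of the others 1, so 1 split gave as many. The listed miRNAs had been selected on the real split, which fixes this outcome, and chance can therefore not be excluded from these counts.

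Some rare miRNAs were listed at 0 throughout a group. In the saline libraries these were miR-344b-3p and 3 numbered candidates, and in the glyoxylate libraries 10 rows, among them miR-670-5p, all with at most 16 reads over the other group's 6 libraries. These names were chosen after their values were seen.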
